A study of Mus musculus with 30 samples.

How the data were processed

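RNA from sorted mouse melanocytes and from keratinocytes was measured on single-colour Illumina bead arrays, 30 in all, in 10 groups of 3. The main deposited table holds the mean bead intensity of 24620 probes on the 27 postnatal arrays, exported from BeadStudio without normalization per the file headers. Beside each intensity the deposited table gives a detection p-value, which in exports of this kind compares the probe with the negative control beads of its array. A separate deposited file holds the unnormalized intensity and detection p-value of 25471 probes on the 3 embryonic arrays; it does not state the software. The authors' series value table holds log2 values of 16378 probes, from 6.60 to 14.5, for the 27 postnatal arrays, and its 3 embryonic columns are empty. Its 27 columns draw on a common pool of 25860 distinct values, with medians from 6.921 to 6.925, as quantile normalization can give. Neither file headers nor labels state the step. Background and scanner settings are not recorded in the files.

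The postnatal intensities were background corrected with 822 negative control probes, quantile normalized and put on a log2 scale with an offset of 16 (neqc of limma 3.58.1 in R 4.3.3). The 8 control-like entries among the probes were left out. A probe entered the tests when its detection p-value was under 0.05 on at least 3 arrays of the fit, which 14441 did. Probes were named through the RefSeq table of assembly GRCm38.p6, used only for names and gene spans: 20513 by accession, 1599 by symbol, 1694 by an older symbol, 576 keeping the symbol of the file and 230 with none. One probe stood for each gene, that with the highest mean over the arrays of the fit, which left 11741 genes. Gene spans are those of that assembly, and 97.8% of tested genes had one.

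The embryonic file carries probe identifiers of another kind than the main table. The value table pairs both kinds, since each of its columns is a monotone function of the intensity on the same array. Its entries were matched to main table probes by their profile over 27 arrays, taken where the next best probe was at least 3 times farther away. This gave 16372 matches, with a median distance of 3.98e-05 to the matched and 0.0438 to the next probe; 6 entries stayed unmatched. Of the embryonic probes 16364 found a partner. As a check, intensities of matched probes on the embryonic arrays and in the main table correlated with Spearman's rho of 0.922 to 0.940 across probes, and near 0 when the match was shuffled. The embryonic file gives no control probes, so the background of its arrays was estimated from signal and detection p-value (normexp.fit.detection.p of limma). The embryonic comparison was fitted on all 30 arrays, quantile normalized together, over 8013 genes, and no other comparison used this match.

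Each comparison was a contrast of group means in limma (lmFit and eBayes, two-sided), with the spread pooled over all 9 postnatal groups (18 residual degrees of freedom) or all 10 groups (20). P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p-value under 0.05. Changes of the UVB effect with time were tested as differences of contrasts. The comparisons against one time point without UV share those arrays. The 30 gene lists, of which 11 mark other cell types, were written from textbook knowledge; 28 name their genes and the ribosomal protein and oxidative phosphorylation lists follow a pattern of symbols. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each as a single family of 360 tests. Members were also adjusted over the list alone. The groups, comparisons, tests, lists, detection rule, rule for named genes and most alternatives were set before the data were examined.

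The rule for named genes took, per comparison, the 10 genes with the highest and the 10 with the lowest change among those called with non-overlapping groups, each from a probe with 1 symbol and passing over clone-style names. For changes of an effect with time it took 5 each way without the overlap condition. From each list it took up to 4 called members with the largest change or, with none called, up to 2 with the smallest p-value, and where fewer than 5 genes passed it took the 5 smallest p-values. The text names a part of these, the first of each ranking and list, with values for a part of those named. Genes that 2 comparisons shared are named in addition. A few results that the rule takes are not reported. Where another detected probe of a gene did not pass or went the other way, the text says so. A gene detected on no array of a group has, in comparisons of 2 groups, a bound on its fold beside the fitted difference: the other group's mean less the lowest level of any detected probe on each undetected array, or the gene's own level there where higher.

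Slide was read from the array positions in the deposited tables. The labels number the replicates, so whether equal numbers pair the samples was checked by correlating deviations from group means across genes. For UVB and no UV at 1 day the correlations were 0.277, 0.256 and 0.597. All were over the bound of 0.1, so the numbers were treated as pairing these samples. Different numbers reached 0.384, so the data do not show that they are pairs. Numbers 1 and 2 lay on slide 1 and number 3 on slide 3, so number and slide overlap. The reported values come from the contrast without the pairing, and the fit with it called 510 genes.

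The steps were tested on simulated data with 200 changed genes among 12968 tested, in the 5 comparisons of UV with no UV. The simulated arrays had independent noise and no slide effect, while real arrays correlated within a slide at 0.589. The shares called are therefore not the power in the real data. For UVB at 1 day they called 16.3% of 1.5-fold, 54% of 2-fold and 82% of 4-fold changes, and 5 of the unchanged genes. For UVB at 6 days they called 39.6% of 2-fold and 89.8% of 4-fold changes, and for UVA at 6 days 36% and 86%.

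The alternatives were no background correction, median scaling of detected probes, the authors' value table, no or a stricter detection filter (detection p-value under 0.01), all probes, the arrays of the groups compared alone, slide as a fixed or random block, the replicate number as a block, array weights, a trended and robust prior, fits within a slide, the 21 day arrays alone, and leaving out each replicate in turn. Leaving out slide 2, the fit within slide 1 for the change of the UVB effect from 1 to 6 days, and the lists under median scaling and without background correction were added after the data were seen. Every other split of the 6 arrays of a comparison, or 100 draws where groups were more, was fitted too, as were, after the data were seen, the 32 splits within replicate numbers for the change of the UVB effect from 1 to 6 days. For the share of keratinocyte RNA, chosen after the data were seen, a marker in the top 5% of levels in keratinocytes allowed at most its ratio of unexposed melanocytes to keratinocytes. A fallen gene needed the part lost after UVB times that ratio. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.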

Results

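The arrays measured RNA from melanocytes sorted out of mouse dorsal skin, and from primary keratinocytes, on single-colour Illumina bead arrays with probes for mouse genes. The mice, on the albino FVB/N background, carried the Dct-rtTA and TRE-H2BGFP transgenes, so that doxycycline, given 24 hours before the postnatal harvests, turned on a green fluorescent histone in cells that use the Dct promoter. Green cells were collected by flow sorting. Pups were exposed on postnatal day 1 to UVB (peak 308 nm, 6 kJ/m2, 15 standard erythemal doses) or to UVA (peak 375 nm, 150 kJ/m2), or were not exposed, and skin was taken 1, 6 or 21 days later. The 30 samples form 10 groups of 3: melanocytes after UVB at 1, 6 and 21 days, after UVA at 1 and 6 days and without UV at 1, 6 and 21 days, embryonic melanocytes of day 17.5, and keratinocytes. The labels name the replicates and the series design calls them biological, so the p-values measure the spread between samples, pooled over all groups of a fit. The median SD of a gene between replicates ran from 0.084 in keratinocytes to 0.30 in melanocytes 6 days after UVA. The pooled spread can therefore differ from that of the groups compared.

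Between 37.6% and 51.4% of the probes were detected per array, and 3 arrays per group limit the precision of every value. The arrays lay on 5 slides, and slide 2 stood apart. Its 8 arrays (UVA at 6 days replicates 1 and 2, the 3 embryonic and the 3 keratinocyte arrays) detected 37.6% to 43.3% of probes, against 46.0% to 51.4% on the other 22. Negative control probes, given for 5 of the 8, averaged 47.9 to 58.6 intensity units there, against 31.6 to 44.1 elsewhere. Changes below are log2 differences ± SE between groups of 3 arrays from limma, with Benjamini-Hochberg adjusted p-values over 11741 genes. Every gene named among the 10 largest changes each way between 2 groups had all 3 arrays of one group above all 3 of the other. Genes named from a list did not have to. The 30 fixed gene lists were tested in all 12 comparisons with camera, in a single family of 360 tests.

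**Figure D1:**
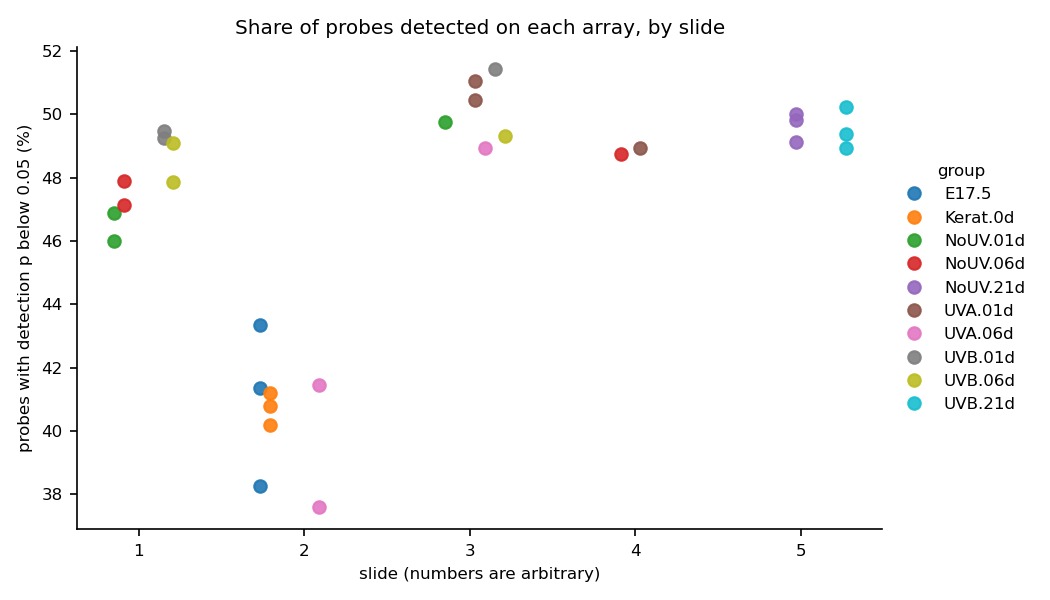
Share of probes detected on each array (y axis, percent), arranged by slide (x axis) and marked by group. The 8 arrays of slide 2 lie between 37.6% and 43.3%, below all 22 arrays of the other slides.

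The comparison of UVB with no UV at 1 day asks which melanocyte genes differ soon after UVB. Interferon-induced and p53 target genes rose, and a set of genes with long spans fell. Keratinocyte markers leaned lower, 8 of 23 passing, but that list call was lost with an estimated correlation (adjusted p = 0.13). Isg15, an interferon-induced ubiquitin-like protein, was higher by 3.13 ± 0.48 (adjusted p = 0.00017), and Usp18, the protease that removes Isg15 from proteins, by 2.54 ± 0.20. Cdkn1a, the p21 inhibitor of cell cycle kinases, was higher by 2.06 ± 0.44 (adjusted p = 0.0055), or 4.17-fold. The largest fall was in Cdh13, a cadherin without a transmembrane part, at -2.63 ± 0.19 (adjusted p = 4.6e-09), although the other Cdh13 probe did not pass. In all, 425 genes passed, 144 higher and 281 lower, and 196 of them changed at least 2-fold (57 higher, 139 lower).

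Of 18 type I interferon response genes tested, 13 rose and none fell (15 adjusted over the list alone; camera adjusted p = 2.2e-25, and adjusted p = 0.0012 with an estimated correlation). They included the antiviral protein Rsad2 at 2.10 ± 0.23 and Bst2, which tethers budding virus, at 1.89 ± 0.32. Of 25 p53 targets, 8 rose and none fell (11 adjusted over the list alone; adjusted p = 5.1e-10, and adjusted p = 0.0012 with an estimated correlation), among them the cyclin Ccng1 at 1.87 ± 0.21, the Akt inhibitor Phlda3 at 1.81 ± 0.26 and Zmat3 at 1.02 ± 0.25. Of 25 interferon-gamma response genes, 4 rose (8 adjusted over the list alone), among them Gbp3, a guanylate-binding protein named Gbp4 in the file, at 2.06 ± 0.30, Irgm2 at 1.59 ± 0.41 and Casp1, the protease that matures interleukin 1 beta, at 0.92 ± 0.20. That call (adjusted p = 0.00078) was lost at adjusted p = 0.53 with an estimated correlation. Of 19 chemokines, Ccl7 (1.59 ± 0.43), Ccl9 (1.42 ± 0.32) and Ccl11 (0.62 ± 0.17) rose, 4 adjusted over the list alone (adjusted p = 0.010, and adjusted p = 0.49 with an estimated correlation). None of 15 MHC class I genes passed, nor any adjusted over the list alone, with a median of 0.47 (adjusted p = 0.00086, and adjusted p = 0.36 with an estimated correlation).

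Of 23 keratinocyte markers, 8 fell and none rose (11 adjusted over the list alone; camera adjusted p = 9.8e-11), a call lost at adjusted p = 0.13 with an estimated correlation. They included the basal keratin Krt15 (-2.29 ± 0.29), the hemidesmosome collagen Col17a1 (-1.90 ± 0.32), the epidermal transcription factor Trp63 (-1.79 ± 0.28) and the desmosome protein Pkp1 (-1.49 ± 0.31). The adhesion list held a single call, the cadherin Cdh3 at -0.95 ± 0.17, which its other probe did not share (list adjusted p = 0.64). Among melanocyte lineage regulators, 1 of 15 passed, Sox9 at -1.46 ± 0.31 (adjusted p = 0.33 for the list). None of 19 melanin synthesis genes passed, and 1 fell adjusted over the list alone; Mlph, which links melanosomes to myosin, stood at -0.79 ± 0.23 (list adjusted p = 0.37). Cd14 (1.23 ± 0.32) was the macrophage and myeloid marker that rose, of 19 (5 adjusted over the list alone; adjusted p = 0.00051, and adjusted p = 0.48 with an estimated correlation). Among 23 matrix remodelling genes the inhibitor Timp1 (1.87 ± 0.29), the protease Plau (0.72 ± 0.17) and Mmp2 (0.68 ± 0.16) rose and Adam12 (-0.98 ± 0.19) fell, 3 and 1 adjusted over the list alone (adjusted p = 0.010, and adjusted p = 0.37 with an estimated correlation).

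Of the S phase list, 1 of 26 fell, Mcm7 of the replication helicase at -0.52 ± 0.12 (1 adjusted over the list alone), though its other probe did not pass. No mitosis gene of 23 passed, over all genes or adjusted over the list alone. Both lists leaned lower by camera (adjusted p = 0.0012 and 0.012), with adjusted p = 0.61 and 0.73 with an estimated correlation. The nucleotide excision repair list had 1 call of 24, Ercc5 (0.59 ± 0.16), which its other probe did not share (list adjusted p = 0.67). The NRF2 list had 1 of 22, the sulfiredoxin Srxn1 (0.97 ± 0.26), which 2 other probes did not share (adjusted p = 0.27). No member of the heat shock (adjusted p = 0.94), immediate early (0.62), MHC class II (0.70), checkpoint (0.92), T and NK cell (0.14), mast cell (0.19), endothelial (0.25), Schwann (0.11), erythroid (0.59) or adipocyte (0.60) lists passed, and adjusted over the list alone only 1 did, an adipocyte marker that was lower. In the hair follicle keratin list Crym (2.01 ± 0.26) rose and Gata3 (-1.07 ± 0.23) fell (adjusted p = 0.63). The fibroblast list had a single fall, Fbln1 (-0.86 ± 0.22), which its other probe did not share (adjusted p = 0.14), and the muscle list a single rise, Tnnt3 (0.46 ± 0.11), at least 1.15-fold, since it was detected on no array without UV (adjusted p = 0.011, and adjusted p = 0.42 with an estimated correlation). No ribosomal protein of 75 passed (adjusted p = 0.045, and adjusted p = 0.46 with an estimated correlation), and 1 of 66 oxidative phosphorylation genes rose, Cox6b2 at 1.15 ± 0.28 (adjusted p = 0.73). The hair follicle keratin list had the same 2 calls adjusted over the list alone, and the adhesion, lineage, repair, NRF2, fibroblast, muscle and oxidative phosphorylation lists the same 1.

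The genes with the largest rises also included Syt4, Crym and Timp1, and those with the largest falls Slc39a11, Supt3, Sdk1, Gmds, Immp2l, Lrba, Bbs9 and Fggy, between -2.56 and -2.23. A split by gene span, chosen after these values were seen, put 198 of the 277 fallen genes with a known span (71.5%) into the longest quintile of tested genes. The median span was 171 kb for the fallen genes, 12.5 kb for the risen genes and 21.0 kb for all. In the longest quintile 8.62% of genes fell, in the shortest 0.784%. A change below -1 was seen in 4.40% and 0.915% of genes there, against 0% in both at 21 days after UVB. The trend over all genes was small. Span and change correlated across 11479 genes, which are not independent replicates, with Spearman's rho of -0.095 at 1 day after UVB. It was -0.0028 at 6 days, -0.11 at 21 days and 0.077 at 1 day after UVA. With slide as a block 922 genes passed, and slide 1 alone (2 arrays per group) gave 342. Slide 3 held 1 array of each of these groups. Its spread would come only from its 2 UVA arrays of 1 day, so no conclusion is drawn from its count. Median scaling put the median change of all genes at 0.14 (log2) and moved the split of called genes from 33.9% to 51.4% higher.

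**Figure D2:**
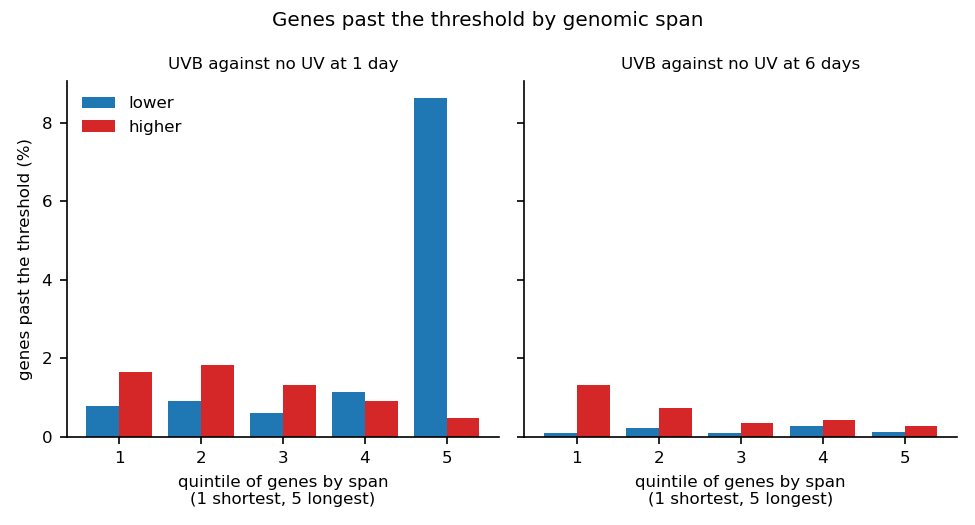
Percent of genes that passed as lower or higher (y axis) in each quintile of gene span, from shortest to longest (x axis), for UVB against no UV at 1 day and at 6 days. At 1 day 8.62% of the longest quintile fell, against 0.784% of the shortest, and at 6 days 0.131% and 0.0871%.

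The comparison at 6 days asks which differences stand later after UVB. Genes of MHC class I antigen processing and of both interferon responses rose. Ccl8, a chemokine that draws monocytes, was higher by 4.30 ± 0.29 (adjusted p = 7.1e-09), at least 15.2-fold, since it was detected on no array without UV. Ctla4, an inhibitory receptor best known from T cells, was higher by 2.81 ± 0.37 (adjusted p = 0.00014), at least 5.39-fold for the same reason. Psmb9, a subunit of the immunoproteasome, was higher by 2.37 ± 0.20 (adjusted p = 3.2e-07) and the non-classical MHC class I gene H2-T23 by 2.32 ± 0.39. In all, 92 genes passed, 74 higher and 18 lower, 67 of them at least 2-fold (52 and 15).

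Of 15 MHC class I genes 6 rose and none fell (11 adjusted over the list alone; camera adjusted p = 2.5e-27, and adjusted p = 0.0012 with an estimated correlation), with H2-K1 at 1.98 ± 0.47 and Psmb8 at 1.42 ± 0.30. Of 18 type I interferon genes 6 rose (14 adjusted over the list alone; adjusted p = 1.9e-28, and adjusted p = 0.0012 with an estimated correlation), including Bst2 (1.63 ± 0.32), Lgals3bp (1.57 ± 0.19), Usp18 (1.55 ± 0.20) and Ifit3 (1.39 ± 0.25). Of 25 interferon-gamma genes 5 rose (15 adjusted over the list alone; adjusted p = 5.7e-23, and adjusted p = 0.040 with an estimated correlation), with Gbp3 at 1.80 ± 0.30. Ccl8 and Ctla4, given above, were among these 5. Of 14 checkpoint genes 4 rose (6 adjusted over the list alone; adjusted p = 1.2e-09, and adjusted p = 0.012 with an estimated correlation), adding Lgals9 (0.97 ± 0.22), which 2 other probes did not share, and Il10 (0.68 ± 0.15, at least 1.20-fold, with no detection without UV). Ccl8 was the single chemokine of 19 to pass (5 adjusted over the list alone; adjusted p = 1.8e-10), and that list lost its call at adjusted p = 0.066 with an estimated correlation.

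Markers of other cells moved as well. Of 19 macrophage and myeloid markers 3 rose (6 adjusted over the list alone; adjusted p = 1.1e-12, and adjusted p = 0.11 with an estimated correlation): the mannose receptor Mrc1 (1.95 ± 0.38), Coro1a (1.31 ± 0.31), which 2 other probes did not share, and Cd52 (0.61 ± 0.13, at least 1.32-fold). Of 15 T and NK cell markers only Il7r passed, at 0.90 ± 0.12 and at least 1.30-fold (as with Cd52, detected on no array without UV; adjusted p = 0.057 for the list). None of 11 MHC class II genes passed and 4 did adjusted over the list alone (adjusted p = 1.8e-06, and adjusted p = 0.12 with an estimated correlation). In the mast cell list Cpa3 rose (1.69 ± 0.35), which its other probe did not share, and Gata2 fell (-1.27 ± 0.29); that call (adjusted p = 0.020) was lost at adjusted p = 0.48 with an estimated correlation. The fibroblast list had a single rise, the proteoglycan Dcn (1.44 ± 0.27), which 2 of 3 other probes did not share, and adjusted p = 0.033, against adjusted p = 0.67 with an estimated correlation. The endothelial list had a single fall, the tight junction gene Cldn5 (-1.94 ± 0.44; adjusted p = 0.92), and the adhesion list a single rise, Cldn1 (0.96 ± 0.21; adjusted p = 0.040, and adjusted p = 0.43 with an estimated correlation).

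None of the 25 p53 targets passed at 6 days (adjusted p = 0.57), nor did any keratinocyte marker, 3 of which were higher adjusted over the list alone (adjusted p = 0.00012, and adjusted p = 0.42 with an estimated correlation). The largest rises also took in Ifi27l2a, H2-Q2, H2-Q5, Cstdc6, Ms4a6d and Ly6a, between 2.37 and 1.99; the other Ms4a6d probe did not pass. The largest falls were in the nucleoside transporter Slc29a4 (-1.68 ± 0.27), Otud7a, the signalling protein Wnt2 (-1.54 ± 0.23), the matrix protein Comp (at least 2.57-fold), Cldn11, Podxl, Homer2, Gdf10, Gja4 and Dtx1 (at least 1.98-fold). Comp and Dtx1 were detected on no array after UVB. Of the genes that rose at 6 days, 14 had also risen at 1 day, where independent lists would share 0.908. They included Ddx58, Ifit3, Gbp3, Usp18, Ifitm3, Bst2, Lgals3bp, Rsad2, H2-T9, Dtx3l, Rnf213, Myo1g and Cyp2d22. A slide block gave 171 genes and within slide 1, the only slide with both groups (2 arrays each), 78. The arrays of the groups compared alone gave 36 and the authors' values 35. The count was 43 without UVB replicate 1, 46 without UVB replicate 2, 60 without UVB replicate 3 and 58 without no UV replicate 2.

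At 21 days a single gene passed between UVB and no UV, Serpina3b, a serine protease inhibitor, at -1.37 ± 0.18 (adjusted p = 0.0012), and 365 genes had an unadjusted p under 0.05. The next smallest p-values belonged to Myoc (-0.84 ± 0.17), the steroid-metabolizing Akr1c18 (-1.22 ± 0.24), Colec12 (-0.46 ± 0.09) and Vit (-0.68 ± 0.14), each with adjusted p = 0.13. Ccl8 averaged 6.44 ± 0.18 after UVB and 6.35 ± 1.05 without (log2 intensity ± SD, n = 3), and Isg15 8.30 ± 0.81 and 7.76 ± 0.93. Replicate 2 of each group stood apart from its group in Isg15: 7.37 after UVB, against 8.71 and 8.82 in replicates 1 and 3, and 8.82 without UV, against 7.39 and 7.06. For Ccl8 only no UV replicate 2 did so, at 7.56 against 5.80 and 5.69. No member of any list passed over all genes, though camera with the preset correlation called 14 lists. It placed T and NK cell markers higher (median 0.27, adjusted p = 2.2e-06, and adjusted p = 0.12 with an estimated correlation; 1 adjusted over the list alone, Cd2 standing at 0.58 ± 0.15). It also placed MHC class I genes higher (median 0.26, adjusted p = 0.00014, and adjusted p = 0.29 with an estimated correlation) and adipocyte markers lower (median -0.39, adjusted p = 0.0017, and adjusted p = 0.16 with an estimated correlation). Endothelial markers (median -0.32, adjusted p = 0.0027) and fibroblast markers (median -0.19, adjusted p = 0.0055) leaned lower, both with adjusted p = 0.56 with an estimated correlation. The other 9 leaned higher, with medians of 0.10 to 0.23, and none was called with an estimated correlation. With the preset and then the estimated correlation they were interferon-gamma (adjusted p = 0.00021, 0.48), oxidative phosphorylation (0.00039, 0.43), melanin (0.0021, 0.56), mitosis (0.0027, 0.66), type I interferon (0.0046, 0.42). They also took in hair follicle keratin (0.021, 0.48), MHC class II (0.030, 0.53), lineage (0.035, 0.49) and checkpoint genes (0.038, 0.46; 3 higher adjusted over the list alone). All 6 arrays lay on slide 5, and a fit of these arrays alone called 0 genes. In simulated data without a slide effect the same limma steps called 66% of 2-fold and 85.7% of 4-fold changes in this comparison. Without UVB replicate 2 it called 20 genes, without no UV replicate 3 it called 6, without no UV replicate 2, 3, and without UVB replicate 3, 2.

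**Figure D3:**
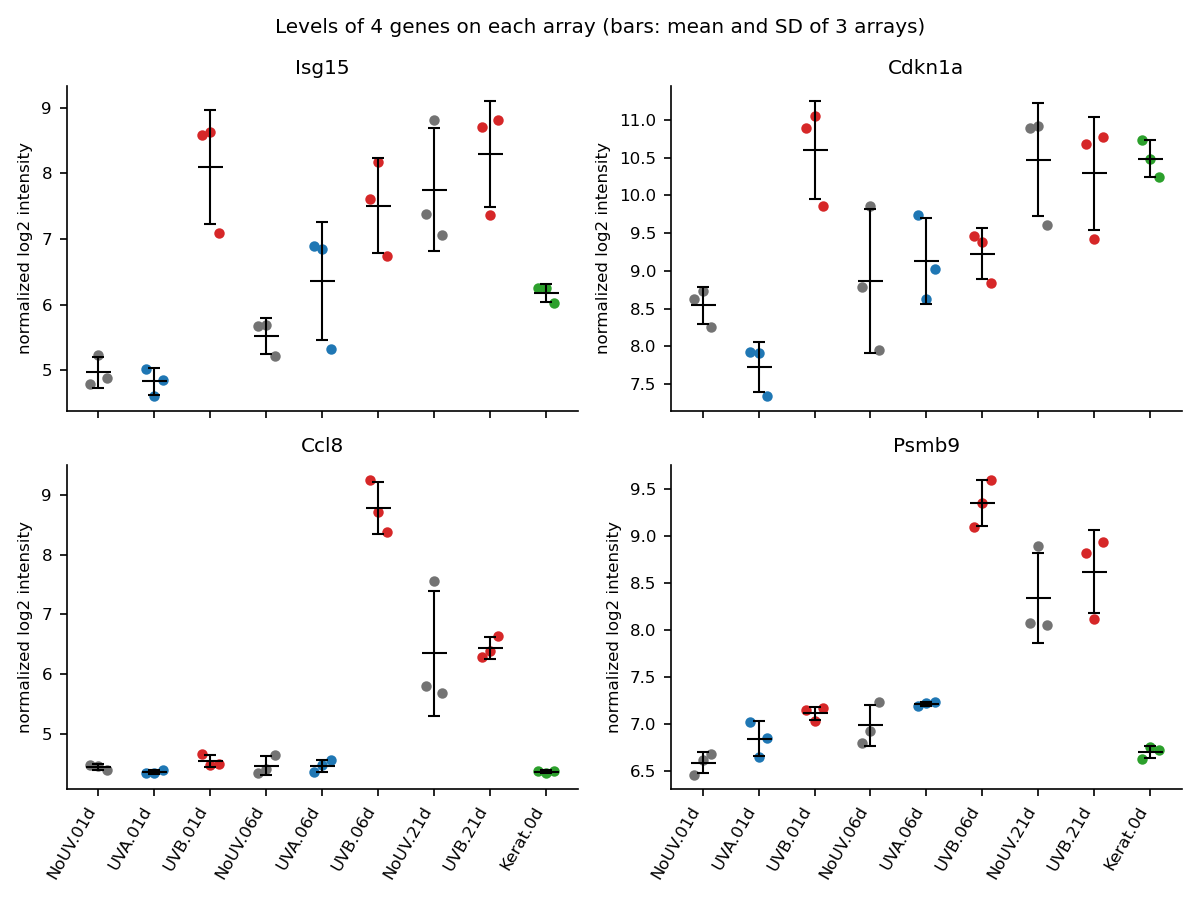
Level (y axis, log2 intensity after normalization) of Isg15, Cdkn1a, Ccl8 and Psmb9 on each array (points) of the 9 postnatal groups (x axis), with mean and SD (bars). Ccl8 averages 8.78 ± 0.44 at 6 days after UVB and 4.48 ± 0.15 without UV, and Cdkn1a 10.60 ± 0.65 and 8.54 ± 0.25 at 1 day.

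UVA against no UV at 1 day asks the same question for the longer wavelength. No gene passed with limma (0 of 11741), and 580 had an unadjusted p under 0.05. The smallest p-values belonged to Adam1a (0.60 ± 0.14), Ift80 (0.75 ± 0.19), the nuclear import gene Kpna4 (-0.52 ± 0.13), the mismatch repair gene Pms1 (0.41 ± 0.11, at least 1.04-fold) and Zfp160 (0.39 ± 0.11, at least 1.01-fold), each with adjusted p = 0.82. Among the lists, keratinocyte markers leaned lower (median -0.16, adjusted p = 0.0053, and adjusted p = 0.56 with an estimated correlation), and no member passed, adjusted over all genes or adjusted over the list alone. In simulated data without a slide effect the same limma steps called 42% of 2-fold and 90% of 4-fold changes in this comparison. With slide as a block 0 genes passed, and with array weights 1661. Slide 3 held 2 UVA arrays and 1 without UV, too few for a count to be relied on. With median scaling the median change of all genes was 0.15.

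UVA against no UV at 6 days gave 1890 genes, 732 higher and 1158 lower, and this comparison is confounded with slide. UVA replicates 1 and 2 lay on slide 2 and replicate 3 on slide 3, and no slide held both groups. The largest falls were in Hmgb1, a chromatin protein, at -3.36 ± 0.54 (adjusted p = 0.00054), the calcium sensor Calm2 (-2.95 ± 0.53), Tuba1a, Stmn1, the chaperonin subunit Cct5, Vps26b and Rps6 (-2.67 ± 0.53). The largest rises were smaller: Tmem140 (1.23 ± 0.20), Gng8, the lipase Lpl (1.04 ± 0.19), Chsy3 and Rsad2 (1.01 ± 0.23). Of 75 ribosomal proteins 22 fell and 1 rose (24 and 4 adjusted over the list alone; adjusted p = 0.00010, and adjusted p = 0.11 with an estimated correlation). Of 14 heat shock genes 6 fell, with the chaperone Hspa5 at -2.48 ± 0.50 and Hspe1 at -2.05 ± 0.35 (6 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.42 with an estimated correlation). Of 22 NRF2 genes 8 fell, with the glutathione reductase Gsr at -1.60 ± 0.32 (10 fell and 1 rose adjusted over the list alone; adjusted p = 0.0073, and adjusted p = 0.16 with an estimated correlation). Of 66 oxidative phosphorylation genes 8 rose and 15 fell, and the list's median of 0.07 and mean of -0.24 differ in sign. S100b (-1.22 ± 0.29; 0.026 with slide 2 left out) was among 3 of 11 Schwann cell genes that fell (4 adjusted over the list alone; adjusted p = 0.0059, and adjusted p = 0.59 with an estimated correlation).

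The falls at 6 days after UVA were also seen on the other arrays of slide 2. Over the 1158 fallen genes the median change was -1.40 in UVA replicates 1 and 2 and -0.25 in replicate 3. Over those of them matched on the embryonic arrays, 788, embryonic against unexposed melanocytes of day 1 gave a median of -1.22. With slide as a fixed block 1 gene passed and the median of the fallen genes was -0.21 (SE of a gene, median 0.24 before and 0.21 after). Leaving out slide 2 left replicate 3 as the only UVA array, too few for a count. With the arrays of the groups compared alone 0 genes passed. That fit takes its spread from fewer arrays at the same changes, so its count does not bear on slide. Limma called 4715 without UVA replicate 3, 578 without replicate 1, 505 without replicate 2 and 1216 without no UV replicate 3. Median scaling put the median change of all genes at -0.17 and moved the split from 38.7% to 2.39% higher.

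UVB against UVA at 1 day asks whether the exposures, which differ in both wavelength and dose, differ in effect. Isg15 (3.27 ± 0.48), Cdkn1a (2.87 ± 0.44) and Usp18 (2.54 ± 0.20, at least 5.44-fold, with no detection after UVA) were higher after UVB, with adjusted p = 9.5e-05, 0.00015 and 1.0e-08. The matrix protein Thbs2 (1.95 ± 0.32) and the small heat shock protein Hspb8 (1.77 ± 0.20) were higher as well. Sdk1 (-2.75 ± 0.24), Cdh13 (-2.61 ± 0.19), which its other probe did not share, Gmds, Lrba, Ptprd and the neuropeptide Npy (-2.50 ± 0.56) were lower. Of 456 genes, 159 were higher and 297 lower after UVB. Of 18 type I interferon genes 12 were higher (14 adjusted over the list alone; adjusted p = 1.5e-22, and adjusted p = 0.0013 with an estimated correlation), and of 25 p53 targets 8, among them Bax, which opens the mitochondrial membrane in apoptosis, at 1.19 ± 0.27 (13 higher and 1 lower adjusted over the list alone; adjusted p = 2.6e-11, and adjusted p = 0.0012 with an estimated correlation). Of 23 keratinocyte markers 6 were lower (7 adjusted over the list alone; adjusted p = 3.9e-05, and adjusted p = 0.39 with an estimated correlation). A block for slide left 604 genes, and slide 3 held 2 UVA arrays and 1 UVB array, too few for a count to be relied on. Of single replicates left out, 252 passed without UVB replicate 2, 298 without UVA replicate 1 and 278 without UVA replicate 2.

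At 6 days UVB and UVA differed in 2495 genes, 1277 higher and 1218 lower after UVB, again with 2 of the 3 UVA arrays on slide 2. Ccl8 (4.31 ± 0.29, at least 12.4-fold), H2-T23 (4.06 ± 0.39), H2-K1 (3.95 ± 0.47) and Ctla4 (2.71 ± 0.37, at least 4.40-fold) were higher, beside Hmgb1 (3.40 ± 0.54) and Stmn1, which had fallen against no UV after UVA. Cldn5 (-2.51 ± 0.44), Ccl21b (-2.49 ± 0.56) and Comp (-2.21 ± 0.29, at least 4.11-fold) were lower. Of 15 MHC class I genes 9 were higher (10 adjusted over the list alone; adjusted p = 1.4e-08, and adjusted p = 0.11 with an estimated correlation). Of 18 type I interferon genes 9 were higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 1.9e-05, and adjusted p = 0.16 with an estimated correlation). Of 19 macrophage and myeloid markers 8 were higher (9 adjusted over the list alone; adjusted p = 8.7e-06, and adjusted p = 0.36 with an estimated correlation), with Cd53 at 1.28 ± 0.24. The NRF2 list had 7 of 22 higher, yet its median was -0.0016 and its mean 0.24 (adjusted p = 0.049, and adjusted p = 0.33 with an estimated correlation). With slide as a block 61 genes passed and with the arrays of the groups compared alone 19. Slide 3 held 1 array of each group, and leaving out slide 2 left 1 UVA array, too few for a count to be relied on. Without single replicates, 643 passed without UVA replicate 2, 821 without UVA replicate 1, 5089 without UVA replicate 3, 1208 without UVB replicate 2 and 1573 without UVB replicate 1. Median scaling put the median change of all genes at 0.21 and moved the split from 51.2% to 94.0% higher.

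The difference between the UVB effect at 6 days and that at 1 day was tested gene by gene, and 236 genes differed, 198 with the higher effect at 6 days. Effects carry their sign, so a gene that fell at 1 day alone has the higher effect at 6 days. Ccl8 (4.2 ± 0.42, adjusted p = 3.5e-06) and Ctla4 (2.72 ± 0.53) were higher after UVB at 6 days. The keratins Krt79 (2.77 ± 0.39) and Krt15 (2.76 ± 0.41) and Cdh13 (2.71 ± 0.27), whose other probe did not pass, had the higher effect at 6 days and were lower after UVB at 1 day. Hspb8 (-2.07 ± 0.29), the cytokine receptor Osmr (-1.68 ± 0.33), Ccng1 (-1.67 ± 0.29), Slc29a4 and Wnt2 had the lower effect at 6 days. Ccl8, Ctla4 and H2-Q7 were detected on no array of the 3 groups other than UVB at 6 days. Slc29a4 and Wnt2 were detected on none at 1 day. These sizes rest on fitted levels near background and have no bound. Of 25 p53 targets 3 had a lower effect at 6 days (6 adjusted over the list alone; adjusted p = 1.7e-06, and adjusted p = 0.012 with an estimated correlation), with Phlda3 at -1.56 ± 0.37 and the DNA polymerase Polk at -1.06 ± 0.23. Of 23 keratinocyte markers 7 had a higher effect at 6 days, with Trp63 at 2.65 ± 0.39 (10 adjusted over the list alone; adjusted p = 3.8e-13, and adjusted p = 0.10 with an estimated correlation). Of 15 MHC class I genes 2 did, Psmb9 (1.84 ± 0.29) and H2-Q7 (0.78 ± 0.19), 4 adjusted over the list alone (adjusted p = 2.0e-05, and adjusted p = 0.22 with an estimated correlation). Blocking by slide gave 452 genes and within slide 1 alone (2 arrays per group) 221. Median scaling put the median change of all genes at -0.12.

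Between the UVB effects at 21 and 6 days 8 genes differed, each with the lower effect at 21 days. Ccl8 (-4.21 ± 0.42, adjusted p = 9.5e-06), Psmb9 (-2.09 ± 0.29), H2-Q2 (-1.96 ± 0.33), Rasgrp1 (-1.65 ± 0.26), whose other probe did not pass, and Serpina3b (-1.37 ± 0.25) led them. Ccl8 was detected on no array without UV at 6 days and Serpina3b on none at 6 days, so these 2 sizes have no bound. Levels without UV were higher at 21 than at 6 days. They were 6.35 against 4.48 for Ccl8, 8.34 against 6.98 for Psmb9 and 11.8 against 9.44 for H2-Q2 (log2 intensity). Rasgrp1 stood at 7.44 against 4.84 and Serpina3b at 6.41 against 4.38. After UVB, Ccl8 (6.44 against 8.78) and Psmb9 (8.62 against 9.35) were lower at 21 days. H2-Q2 (12.1 against 11.7), Rasgrp1 (7.07 against 6.11) and Serpina3b (5.04 against 4.37) were not. The type I interferon list had no call over all genes and 6 lower adjusted over the list alone (median -0.77, camera adjusted p = 6.2e-14, and adjusted p = 0.012 with an estimated correlation). For MHC class I the counts were 1 and 5 (adjusted p = 4.1e-11), and the call was lost at adjusted p = 0.056 with an estimated correlation. The 21 day arrays shared slide 5 with no other time, so time and slide cannot be separated in the means, though each effect was taken within its own time. A slide block gave 53 genes and with slide 2 left out 13. Limma called 25 without UVB at 21 days replicate 2 and 14 without no UV at 6 days replicate 2.

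Unexposed melanocytes of day 1 were set against keratinocytes to show which genes mark the sorted cells. Pigment genes were higher in melanocytes, with the melanosome protein Tyrp1 at 7.62 ± 0.38 and Mlana at 6.51 ± 0.20, and Vgll2, detected on no keratinocyte array, at least 116-fold. Trpm1, a melanocyte ion channel, was at least 76.3-fold higher, though 2 other probes did not share it. Keratins of the upper epidermis were lower: Krt1 (-8.23 ± 0.19) by at least 244-fold, Krt16 (-6.98 ± 0.20) by at least 98.2-fold and Krt10 (-6.49 ± 0.30), with the cornified envelope protein Lor at -7.05 ± 0.93. Of 6972 genes 3262 were higher and 3710 lower. The melanin list had 16 of 19 members higher and none lower (17 adjusted over the list alone; adjusted p = 7.4e-11, and adjusted p = 0.16 with an estimated correlation). The lineage list had 11 of 15 higher, with Ednrb (5.23 ± 0.16), Sox10 (4.86 ± 0.21) and Kit (4.70 ± 0.22), and 3 lower (11 and 3 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.29 with an estimated correlation). Of 23 keratinocyte markers 20 were lower and 2 higher (20 and 2 adjusted over the list alone; adjusted p = 5.0e-09, and adjusted p = 0.16 with an estimated correlation).

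Markers of further cell types were higher in the sorted melanocytes than in keratinocytes. Of 22 fibroblast markers 19 were higher, with the collagens Col3a1 (6.67 ± 0.48, at least 55.7-fold) and Col1a1 (6.66 ± 0.29, at least 73.5-fold), and 3 lower (19 and 3 adjusted over the list alone; adjusted p = 6.5e-06, and adjusted p = 0.33 with an estimated correlation). Of 15 endothelial markers 13 were higher, with Esam (3.87 ± 0.30) and Robo4 (3.72 ± 0.36, at least 7.19-fold) (13 adjusted over the list alone; adjusted p = 5.4e-07, and adjusted p = 0.33 with an estimated correlation), and of 11 Schwann and neural crest glia genes 9, with the myelin gene Mbp (6.88 ± 0.26) (9 adjusted over the list alone; adjusted p = 1.7e-05, and adjusted p = 0.40 with an estimated correlation). Of 15 T and NK cell markers 11 were lower (11 adjusted over the list alone; adjusted p = 0.0055, and adjusted p = 0.42 with an estimated correlation). All keratinocyte arrays lay on slide 2 with no unexposed melanocyte array, and a slide block, tied through the UVA arrays, left 3624 genes. Median scaling put the median change of all genes at 0.51 and moved the split from 46.8% to 69.8% higher, and it turned the median of the p53 list from -0.68 to 0.10.

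Unexposed melanocytes of 6 days against 1 day show the change with age. Proliferation genes fell: of 26 S phase genes 19, with Tk1 (-1.62 ± 0.38), whose other probe did not pass, and the helicase subunit Mcm6 (-1.60 ± 0.32) (23 adjusted over the list alone; adjusted p = 2.7e-24, and adjusted p = 0.078 with an estimated correlation). Of 23 mitosis genes 17 fell, with Birc5 (-1.69 ± 0.40), the cyclin Ccnb1 (-1.65 ± 0.33) and Kif23 (-1.61 ± 0.35) (20 adjusted over the list alone; adjusted p = 2.6e-20, and adjusted p = 0.11 with an estimated correlation). Of 22 fibroblast markers 12 fell, with Dcn at -2.71 ± 0.27, which 1 of 3 other probes did not share, and Lum at -2.44 ± 0.38, at least 4.48-fold (undetected at 6 days; 15 adjusted over the list alone; adjusted p = 3.8e-14, and adjusted p = 0.078 with an estimated correlation). Of 15 endothelial markers 7 fell, with Robo4 (-2.36 ± 0.36) (10 adjusted over the list alone; adjusted p = 3.3e-07, and adjusted p = 0.33 with an estimated correlation). The T cell receptor chains Cd3g (2.37 ± 0.28) and Cd3e (2.31 ± 0.27, at least 4.11-fold) were among 5 of 15 T and NK cell markers that rose (6 adjusted over the list alone; adjusted p = 3.5e-05, and adjusted p = 0.16 with an estimated correlation). The largest rises were Snorc (6.63 ± 0.82), the lipocalin Apod (3.41 ± 0.34) and Retnla (3.06 ± 0.51, at least 6.28-fold), and the largest falls the collagen cross-linking enzyme Lox (-3.68 ± 0.39) and Car4 (-3.28 ± 0.32). Of 794 genes 288 rose and 506 fell. Blocking by slide gave 1341 genes, the fit within slide 1 (2 arrays per group) 497, with the arrays of the groups compared alone 392, without no UV at 1 day replicate 1 457 and without no UV at 6 days replicate 2 499.

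Embryonic melanocytes against unexposed melanocytes of day 1 were compared over 8013 genes whose probes could be matched between the deposited files by their values, and 3676 differed, 2110 higher and 1566 lower in the embryo. Rasgrp3 (3.39 ± 0.29), the haemoglobin chain Hba-a1 (3.37 ± 0.41) and the chemokine Ccl3 (3.17 ± 0.29, at least 7.89-fold) were higher, and Npy (-5.04 ± 0.57), the basal keratin Krt14 (-4.74 ± 0.18) and Hmgb1 (-4.53 ± 0.53) lower. Of 14 keratinocyte markers 9 were lower (9 adjusted over the list alone; adjusted p = 8.4e-07, and adjusted p = 0.11 with an estimated correlation). Of 11 lineage regulators 6 were lower, with Tfap2b (-2.76 ± 0.30) and Mitf (-2.17 ± 0.46), the master regulator of pigment cells, which turned to 0.32 with slide as a fixed block (6 adjusted over the list alone; adjusted p = 0.0055, and adjusted p = 0.16 with an estimated correlation). Of 16 macrophage and myeloid markers 9 were higher, with Cd14 at 2.76 ± 0.33, and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0055, and adjusted p = 0.50 with an estimated correlation). Of 5 erythroid markers 4 were higher (4 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.23 with an estimated correlation), and of 6 muscle markers 5, with Tnnc1 (2.12 ± 0.24, at least 3.77-fold) (5 adjusted over the list alone; adjusted p = 0.0027, and adjusted p = 0.28 with an estimated correlation). All embryonic arrays lay on slide 2 without a day 1 array, and a slide block, tied through the UVA arrays, left 305 genes. Median scaling put the median change of all genes at -0.40 and moved the split from 57.4% to 31.7% higher.

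Across the 360 list tests, camera with its preset correlation made 134 calls, fry 73, and camera with an estimated correlation 10, all of them among the 134. Those that held were the type I interferon list for UVB at 1 and 6 days, for UVB against UVA at 1 day and for the change of the UVB effect between 6 and 21 days. The p53 list held for UVB at 1 day, for UVB against UVA at 1 day and for the change of the UVB effect between 1 and 6 days. MHC class I, interferon-gamma and checkpoint genes held for UVB at 6 days. These lists are not separate evidence, since Ctla4 is in the interferon-gamma and checkpoint lists and H2-T23 in the MHC class I and checkpoint lists. The share of genes whose groups did not overlap was 18.2% for UVB at 1 day, 10.9% at 6 days, 9.67% at 21 days, 12.9% for UVA at 1 day and 16.3% at 6 days, where chance gives 10%.

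**Figure D4:**
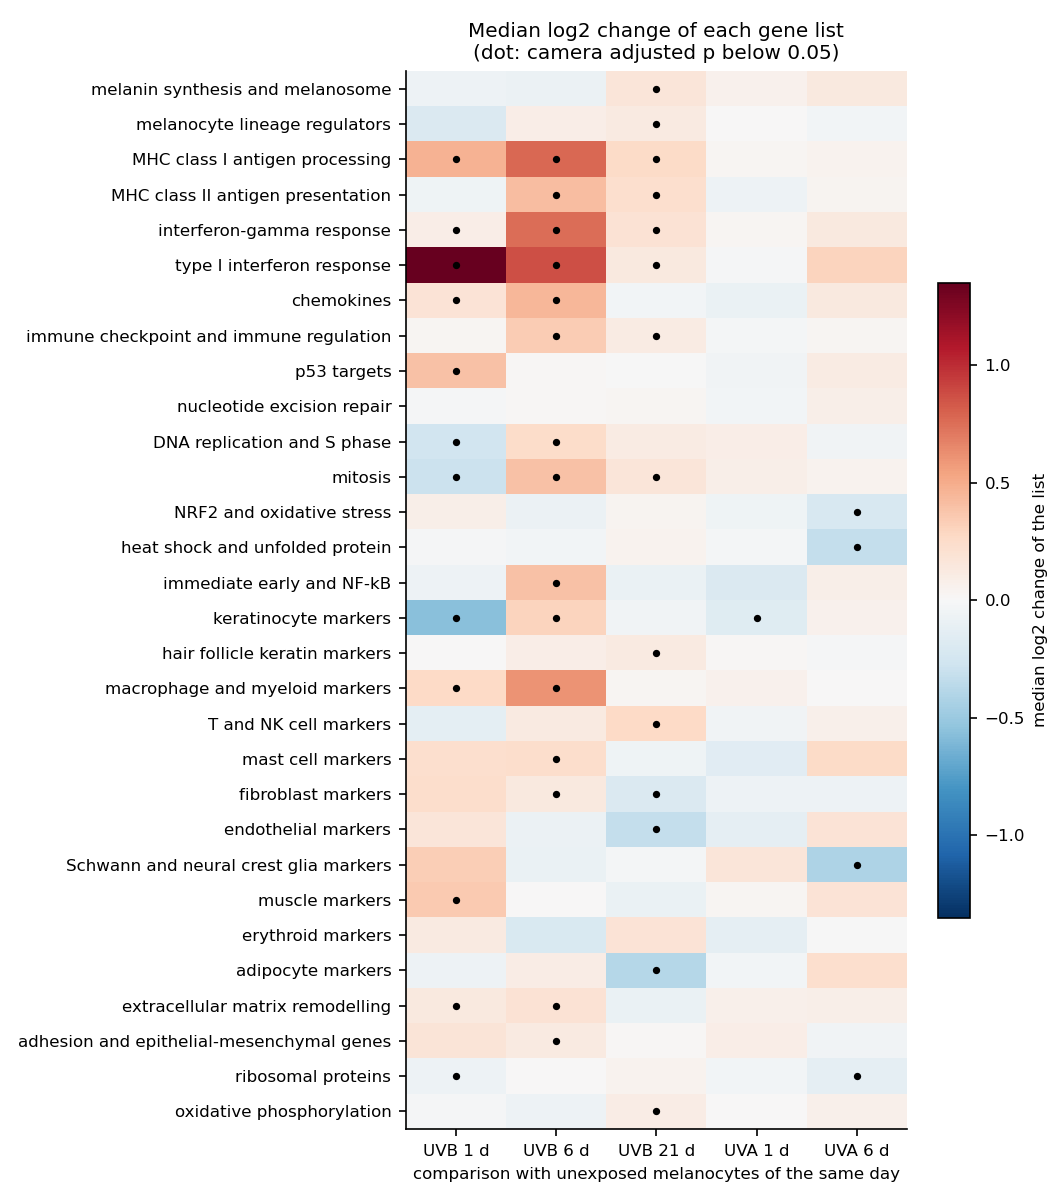
Median log2 change (colour) of the 30 gene lists (rows) in the 5 comparisons of UV with no UV (columns); a dot marks camera adjusted p below 0.05 with the preset correlation. The type I interferon list is at 1.35 and 0.87 after UVB at 1 and 6 days, and -0.01 after UVA at 1 day.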

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

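Chosen only after the results were seen were the tests of slide 2 and of UVA exposure at 6 days, of gene span, of the share of genes below -1 within a slide, of keratinocyte RNA outside the longest quintile, of the share of keratinocyte RNA, of splits within replicate numbers, and of myeloid and of T and NK cells. The last 2 took the place of earlier tests against called members and Ctla4, which had been picked for the size of their change. The UVB effect differed between 6 days and 1 day in 236 genes and between 21 and 6 days in 8 genes, by the tests of the difference itself. In 100 draws of the group labels, 2 gave as many as 236, the real one included. The other, with 312, kept the 2 replicate 3 arrays of each time, off slide 1, together, which points to a structure of the samples; slide as a block gave 452. Replicate numbers partly pair these samples, and 2 of the 32 splits that exchange UVB and no UV within numbers gave as many: the real one and one with 291 that exchanged every number at 1 day, which adds the UVB effects up. The 24 of them that mixed the groups at 1 day gave at most 17. The 100 draws ignore the partial pairing, so their share of 2 in 100 does not exclude chance for the 236. The splits within numbers cannot decide either. The split that adds the effects up gives a large count wherever UVB acted at either time, and 2 of 32 is not under 0.05. Given the partial pairing, chance is therefore not excluded here. For the 8 genes it cannot be excluded: 21 of 100 draws gave as many, up to 73, and draws with several times the real count point to a structure of the samples.

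The first pattern is the 1890 genes called between UVA and no UV at 6 days. A shift of the arrays on slide 2 is a candidate explanation: the genes called lower had a median of -1.22 on the embryonic arrays, also on slide 2, against unexposed melanocytes of day 1, and -1.40 in UVA replicates 1 and 2, but -0.25 in replicate 3 on slide 3. Across 7957 genes, which are not independent replicates, the change in replicates 1 and 2 correlated with the embryonic change at r = 0.74 and that in replicate 3 at r = -0.0039; the 2 differences share no array. With slide as a fixed block the median went from -1.02 to -0.21 and the SE of a gene from 0.24 to 0.21 (medians), and 1 gene passed, so the calls ended with the size of the change. UVA exposure cannot be told apart from slide for what remains, because 1 UVA array lay off slide 2 and no slide held both groups.

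The next pattern is the fall of long genes 1 day after UVB. The share called lower was 11 times as high in the longest quintile of spans as in the shortest, and a hypothesis is that UVB lowers the RNA of long genes in melanocytes. Against slide as the cause, the share of genes below -1 was 3.67 times as high in the longest quintile within slide 3 (1 array per group). It was 5.37 times as high within slide 1 (2 arrays per group). An earlier test by medians met its bound for slide (above -0.1) at -0.047 within slide 3. All arrays together met it too, at -0.059, so it could not decide, and the test by shares was chosen after it. The span trend over all genes was as large at 21 days (rho -0.11) as at 1 day (-0.095). Less keratinocyte RNA is a candidate for the fallen genes outside the longest quintile, 79 in number. They were lower in unexposed melanocytes than in keratinocytes by a median of -2.50 (95% bootstrap interval -3.17 to -1.82). The same unexposed arrays enter both differences. Their falls would need a median share of keratinocyte RNA of 0.0743 (quartiles 0.0476 and 0.242), or 0.122 (0.0547 and 0.286) with slide as a block. Without the keratinocyte list, the other 72 would need 0.0825 (0.0476 and 0.254). These medians lie above those that the abundant markers allowed, given below, but the quartile ranges overlap, so the shares do not decide. For the 198 in the longest quintile less keratinocyte RNA is argued against by most markers. Their falls would need a median share of 0.447 (0.254 and 0.808), or 0.507 (0.310 and 0.935) with slide as a block. The 14 abundant markers allowed 0.0397 (0.0289 and 0.129), or 0.0618 (0.0209 and 0.170) with the block. Krt5 stood at 7.47 against 12.7 in keratinocytes and Krt10 at 7.32 against 13.8. Without the 64 called higher in melanocytes than in keratinocytes, the other 134 would need 0.318 (0.175 and 0.475). That range holds what Krt14 (12.2 against 14.0, and 11.1 after UVB), Krt15 and Krt17 allowed, 0.291, 0.300 and 0.390. For the 134 the argument thus rests on the other markers. A test by medians, at -0.15 (-0.31 to 0.10), had not decided. Of 23 markers 18 were detected on every unexposed array and 2 are in another list. The keratinocyte arrays all lay on slide 2. Keratinocytes unlike those measured stay open, and the sort for green cells does not exclude them, since keratinocyte markers were detected after it.

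The last pattern is the rise of MHC class I and interferon genes 6 days after UVB, where 17 called members rose by a median of 1.55. Slide is argued against by a median of the MHC class I list of 0.81 within slide 1 and 0.84 with slide as a block (0.77 over all arrays). Added myeloid cells cannot be told apart from a response of other cells: the macrophage and myeloid list had a median of 0.61 and an upper quartile of 0.98, against a median of 0.77 for all 58 tested members of the MHC class I and interferon lists (0.78 and 0.82 within slide 1), while its abundant gene Lyz2 stood at 7.16 without UV and 7.28 after UVB (log2 intensity); 13 of its 19 members were detected on every unexposed array, and no other list holds any of them. Added T and NK cells are argued against by a median of 0.12 and an upper quartile of 0.35, with Cd3e at 6.91 and 6.96; of that list 7 of 15 members were detected on every unexposed array and none is in another list. The source stays open between added myeloid cells, cells of other kinds and a response to UVB. That response, a hypothesis found and tested on the same data, could be of melanocytes or of myeloid cells already present. The sort for green cells does not exclude other cells, since 13 of 19 myeloid and 7 of 15 T and NK cell markers were detected on every unexposed array.

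For comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. UVB against no UV gave 425 genes at 1 day (1 split as large, the real one; highest other 5), 92 at 6 days (1, highest other 0) and 1 at 21 days (7 splits, highest other 150, with UVB replicates 1 and 3 and no UV replicate 2 on one side). That split called many times the real count, which points to a structure of the samples at 21 days. For the samples treated as pairs at 1 day, the 3 other splits that part all pairs gave 0 genes each. UVA against no UV gave 0 at 1 day (10, highest other 1) and 1890 at 6 days (3, highest other 3413). UVB against UVA gave 456 at 1 day (1, highest other 0) and 2495 at 6 days (2, highest other 2808). The 3413 split kept UVA replicates 1 and 2, on slide 2, with no UV replicate 1, another that followed slide 2 gave 2225, and the 2808 split kept them with UVB replicate 1; with slide as a block the real counts were 1 and 61. Melanocytes against keratinocytes gave 6972 (1, highest other 0), 6 days against 1 day without UV 794 (1, highest other 3) and embryonic melanocytes 3676 (1, highest other 39). For the 134 calls of gene lists, 64 of 100 draws of all labels gave as many, up to 193, so chance cannot be excluded for their number; these draws mix cell types and slides, which is a structure of the samples.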

How the results depend on the processing

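Leaving out slide 2 was chosen after the data were seen. So was the fit within slide 1 for the change of the UVB effect from 1 to 6 days. So were the gene lists under median scaling and without background correction. Unless stated, the cause was not tested for any change of a count given here. Within slide 3 the spread comes only from its 2 UVA arrays of 1 day, and every other group there has 1 array. Without slide 2, 1 UVA array of 6 days is left. Counts within slide 3, and that without slide 2 for UVB against UVA at 6 days, therefore rest on groups of 1 array. They are listed only for completeness, and no conclusion is drawn from them. Counts for UVB against no UV at 1 day, 425 in the report, were 268 with the authors' values, 922 and 832 with slide as a fixed and a random block, 1359 with array weights and 639 within slide 3. At 6 days, 92 became 35 with the authors' values, 36 with the arrays compared alone (a spread from fewer arrays), 171 and 179 with slide as a fixed and a random block and 141 with weights. At 21 days, 1 became 0 with median scaling, with the arrays compared alone and with those arrays normalized and fitted alone, 2 with the authors' values, 3 without a detection filter, 3 with a trended and robust prior, 11 with a random slide block and 240 with weights. UVA at 1 day, with 0, gave 1661 with weights and 9 within slide 3. UVA at 6 days, with 1890, gave 1237 with the authors' values, 0 with the arrays compared alone, 1 and 59 with slide as a fixed and a random block and 4343 with weights.

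UVB against UVA at 1 day, with 456, gave 283 with median scaling, 295 with the authors' values, 3820 with weights and 1025 within slide 3. At 6 days, 2495 became 1616 with the authors' values, 19 with the arrays compared alone, 61 and 204 with slide as a fixed and a random block, 5736 with weights, 106 within slide 3 and 42 without slide 2. The change of the UVB effect from 1 to 6 days, 236, became 132 with median scaling, 133 with the authors' values, 452 and 434 with slide as a fixed and a random block and 478 with weights; that from 6 to 21 days, 8, became 2 with median scaling, 3 with the arrays compared alone, 53 and 64 with slide as a fixed and a random block, 142 with weights and 13 without slide 2. Melanocytes against keratinocytes, 6972, gave 4629 with the authors' values and 3624 and 4597 with slide as a fixed and a random block. The 6 against 1 day comparison without UV, 794, gave 466 with the authors' values, 392 with the arrays compared alone, 1341 and 1268 with slide as a fixed and a random block and 497 within slide 1. The embryonic comparison, 3676, gave 305 and 1239 with slide as a fixed and a random block, and was not run on the authors' values, where its columns are empty. Of 134 list calls, 10 remained with an estimated correlation, and fry made 73, sharing 60.

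The replicate block gave 510 for the samples treated as pairs at 1 day. For comparisons whose samples share only a number it gave 38 for UVB at 6 days, 0 at 21 days, 0 for UVA at 6 days, 232 and 2 for UVB against UVA at 1 and 6 days, 0 for the change of the UVB effect to 21 days and 2427 for the embryo. For the change to 6 days, where 4 of the 6 pairs of groups had every correlation over 0.1 and UVB at 6 and 1 days had 0.449, 0.367 and 0.636, it gave 396. It changed no other count by over 1.5 times. In none of the comparisons of 2 groups did every sample correlate best with its own number.

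Leaving out each replicate in turn gave 298 to 385 for UVB at 1 day, 43 to 75 at 6 days, 1 to 20 at 21 days, 0 to 0 for UVA at 1 day, 505 to 4715 at 6 days, 252 to 612 and 643 to 5089 for UVB against UVA at 1 and 6 days, 180 to 242 and 6 to 25 for the changes of the UVB effect, 6404 to 6577 against keratinocytes, 457 to 691 for 6 against 1 day and 2975 to 3525 for the embryo. Moves over 1.5 times came, for UVB at 6 days, without UVB replicate 1 (43), 2 (46) and 3 (60) and no UV replicate 2 (58); at 21 days without UVB replicates 2 (20) and 3 (2) and no UV replicates 2 (3) and 3 (6); for UVA at 6 days without UVA replicates 1 (578), 2 (505) and 3 (4715) and no UV replicate 3 (1216); for UVB against UVA at 1 day without UVB replicate 2 (252) and UVA replicates 1 (298) and 2 (278), and at 6 days without UVB replicates 1 (1573) and 2 (1208) and UVA replicates 1 (821), 2 (643) and 3 (5089); for the change to 21 days without UVB at 21 days replicate 2 (25) and no UV at 6 days replicate 2 (14); for 6 against 1 day without no UV at 1 day replicate 1 (457) and at 6 days replicate 2 (499).

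Median scaling moved the share of higher calls from 33.9% to 51.4% for UVB at 1 day, 38.7% to 2.39% for UVA at 6 days, 51.2% to 94.0% for UVB against UVA at 6 days, 46.8% to 69.8% against keratinocytes and 57.4% to 31.7% for the embryo. Genes named in the text were counted once per comparison, which gave 200 called pairs of gene and comparison. Of their 4025 values over all alternatives, 3497 kept direction and call, 526 kept direction only and 2 turned. S100b after UVA at 6 days was at 0.026 without slide 2, and Mitf in the embryo at 0.32 with slide as a fixed block. Of 253 values of genes not called, 33 passed. Signal over background limits the dimmer genes, since 37.6% to 51.4% of probes were detected per array.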

Other observations

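Of the list tests that follow, those with median scaling were chosen after the results were seen. In unexposed melanocytes of day 1 against keratinocytes, 13 of 19 genes of the adhesion and epithelial-mesenchymal list were higher and 3 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.0055, and adjusted p = 0.28 with an estimated correlation). The transcription factors Zeb2 (4.92 ± 0.36), Zeb1 (3.39 ± 0.16, at least 6.36-fold) and Snai1 (2.33 ± 0.30, at least 3.10-fold) and the intermediate filament Vim (2.26 ± 0.13) were among the higher ones, and epithelial cadherin Cdh1 averaged 9.47 in these melanocytes and 8.60 in keratinocytes (log2 intensity). Chemokines went both ways, with 5 of 19 higher and 4 lower (the same counts adjusted over the list alone; adjusted p = 0.96): Cxcl12, which guides migrating pigment cells, was higher by 4.46 ± 0.19, and the skin chemokines Cxcl14 (-3.56 ± 0.24) and Ccl27a (-3.21 ± 0.24) were lower. Of 11 MHC class II genes 7 were lower, with H2-DMa at -2.36 ± 0.31 and the invariant chain Cd74 at -1.80 ± 0.35, but the list did not pass (7 adjusted over the list alone; adjusted p = 0.062). Of 14 heat shock genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone), with the chaperone Hsp90aa1 at 3.40 ± 0.47; that call (adjusted p = 0.012) stood at adjusted p = 0.13 with median scaling and adjusted p = 0.49 with an estimated correlation. Of 22 NRF2 genes 13 were higher, with the iron store Fth1 at 2.96 ± 0.28, and 4 lower (13 and 4 adjusted over the list alone; adjusted p = 0.045, adjusted p = 0.27 with median scaling and adjusted p = 0.33 with an estimated correlation). All keratinocyte arrays lay on slide 2.

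Between 1 and 6 days without UV further cell type markers moved. Smooth muscle actin Acta2 (-2.44 ± 0.48), which 1 of 2 other probes did not share, and the myosin Myh11 (-1.76 ± 0.36) were among 3 of 8 muscle markers that fell (3 adjusted over the list alone; adjusted p = 0.00042, and adjusted p = 0.21 with an estimated correlation). Of 5 adipocyte markers 3 fell, with Adipoq at -1.03 ± 0.24, at least 1.77-fold (4 adjusted over the list alone; adjusted p = 7.4e-05, and adjusted p = 0.078 with an estimated correlation). Of 23 keratinocyte markers 6 fell, with Krtdap at -2.14 ± 0.43 and Krt17 at -1.17 ± 0.26 (8 adjusted over the list alone; adjusted p = 8.9e-05, and adjusted p = 0.42 with an estimated correlation). Of 11 MHC class II genes H2-Ab1 (1.62 ± 0.33) and Cd74 (1.44 ± 0.35) rose and Ifi30 (-0.68 ± 0.14) fell (5 and 1 adjusted over the list alone; adjusted p = 0.033, and adjusted p = 0.54 with an estimated correlation). At 6 days after UVB, camera placed 4 further lists higher although none of their members passed. These were S phase (median 0.25, adjusted p = 3.9e-05, and adjusted p = 0.50 with an estimated correlation), mitosis (0.40, adjusted p = 0.00013, and adjusted p = 0.56 with an estimated correlation), immediate early and NF-kB genes (0.40, adjusted p = 1.7e-05, and adjusted p = 0.49 with an estimated correlation; 2 adjusted over the list alone) and matrix remodelling (0.20, adjusted p = 0.0056, and adjusted p = 0.33 with an estimated correlation). The cytokine Il1b stood at 1.14 ± 0.34 (adjusted p = 0.19) and Tnfaip3, which restrains NF-kB, at 1.21 ± 0.35 (adjusted p = 0.15).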
